A study of Homo sapiens with 6 samples.

How the data were processed

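OVCAR8 cells were sequenced as 6 RNA libraries, 3 treated with PBS and 3 with leptin (100 ng/ml, 24 h, after overnight serum starvation). Per the labels' protocols, libraries were prepared from total RNA with a directional kit and sequenced as paired ends. The deposited values are raw fragment counts per gene, 1 table per library. Per the file headers, the authors counted read pairs over exons, summed per gene of GENCODE release 44, with featureCounts 2.0.1, with no strand option and without the options that count multi-mapping reads or reads over several genes. The submitters' processing notes name HISAT2 2.0.5, hg38, DESeq2 and featureCounts 1.5.0-p3, a version that differs from the one in the file headers. Counted without strand and without the option for several genes, read pairs over exons of 2 overlapping genes are left out even where the genes lie on opposite strands, which lowers the counts of such genes. Leaving out multi-mapping reads lowers the counts of genes with near-identical copies. Trimming and read filters are not given in the sources used here.

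Each table held 62700 gene IDs, and all were matched to a symbol. A gene type was found for 58600 IDs, from GENCODE release 29 for 58207 and by symbol from RefSeq for 393. Coordinates are those in the files. No count fell on any of the 37 mitochondrial genes, and 29872 genes had no count in any library. Totals per library lay between 15609425 and 18577775. There were 0 other columns of per-sample values. In all same-group pairs the counts differed by more than sampling noise (chi-square per gene between 5.31 and 46.7), so each library counted as 1 sample.

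The groups were compared in R 4.3.3 with edgeR 4.0.16 on the counts as deposited: filterByExpr with a minimum count of 10 and a minimum total of 15, TMM scaling, robust quasi-likelihood fits without a replicate block, and Benjamini-Hochberg adjustment with a threshold of 0.05. A change of at least 2-fold was an absolute log2 fold change of at least 1. CPM values use TMM-scaled totals, standard errors are those implied by the fold change and the F statistic, and log2 CPM for principal components used a prior count of 2. From 37 gene lists fixed before the data were examined, the 33 with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The common biological coefficient of variation was 0.150.

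Genes were named by a rule fixed before the data were examined. It takes LEP, LEPR, JAK2, STAT3 and SOCS3, the 12 protein-coding genes with the largest log2 fold change in each direction among those past the threshold with a mean CPM of at least 1 and no overlap between the groups, and up to 4 genes per list with the smallest adjusted p. The limit of a count of 0 was set at 3 counts.

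Other alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, an adjusted p under 0.01, a length trend, a replicate block and leaving out each library. Removal of each library's GC trend (lowess with a span of 0.3 on the GC content of the longest transcript, entered as offsets) was chosen after seeing the data. GC content was known for 97.2% of tested genes and 99.2% of called genes. In simulated data for this comparison, over 15685 genes, edgeR recovered 79 of 100 genes changed 2-fold and 96 of 99 changed 4-fold, and called 9 unchanged genes. Genes were simulated as independent and with the same spread in both groups. In the deposited data the median SD of log2 CPM was 0.12 in controls and 0.24 with leptin, so these numbers do not estimate the error rates there. A GC trend simulated in the leptin libraries alone made 4164 unchanged genes pass, and 5 passed after its removal. The 4164 exceed the 1538 genes called in the deposited data. They test the removal step and do not estimate how many calls the GC trend of these libraries produced. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, with 0.1 CPM added before the logarithm.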

Results

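Gene expression was measured by RNA sequencing in OVCAR8 cells, an established human ovarian carcinoma cell line. The cells had been kept without serum overnight and then received either PBS or the adipocyte hormone leptin at 100 ng/ml for 24 h. There were 3 control and 3 leptin libraries. Total counts assigned to genes lay between 15609425 and 18577775 per library, and the deepest library held 1.19 times the counts of the shallowest. Mean totals differed by less than the spread between replicates (exact two-sided permutation p = 0.8 over 5 library measures, adjusted p = 0.8; 3 libraries against 3 cannot give a p below 0.1). The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The stated purpose of the comparison was to find transcripts downstream of leptin that relate to stem-like properties of ovarian cancer cells.

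The leptin receptor gene LEPR was expressed in these cells, at 15.5 ± 0.924 CPM (counts scaled to library size) in controls and 11.6 ± 2.86 CPM with leptin (mean ± SD, n = 3 each). Its log2 fold change of -0.41 ± 0.18 (SE) did not pass edgeR's quasi-likelihood test (adjusted p = 0.165). The receptor-associated kinase gene JAK2 stood at 8.13 ± 1.5 and 9.15 ± 0.608 CPM, with a log2 fold change of 0.17 ± 0.18 (edgeR adjusted p = 0.589). STAT3, the transcription factor that this receptor activates, stood at 354 ± 12.9 and 365 ± 37.3 CPM (log2 fold change 0.04 ± 0.12, edgeR adjusted p = 0.847). The feedback inhibitor SOCS3 stood at 36.6 ± 4.10 and 35.0 ± 12.4 CPM (log2 fold change -0.06 ± 0.21, edgeR adjusted p = 0.876). This small mean change of SOCS3 averaged opposite shifts. Leptin replicate 1 stood at 49.1 CPM, above every control. Leptin replicates 2 and 3 stood at 25.7 and 30.1 CPM, below every control. LEP, which encodes leptin, had 0 counts in all 6 libraries, and 3 counts, taken as the limit of a count of 0, equal 0.161 to 0.192 CPM. This limit covers counting error only. Of 24 tested genes of the leptin receptor and JAK-STAT signalling list, 2 rose: the cytokine-signalling suppressor SOCS2, from 10.8 to 20.4 CPM, and the JAK2 adaptor SH2B1, from 58.7 to 80.4 CPM. The count adjusted over the list alone was also 2. The list as a whole did not pass camera (adjusted p = 0.654). Among 28 tested STAT3 target genes, ICAM1, VEGFA and CEBPB rose, while FOS and TIMP1 fell; CEBPB was named after its values were seen. That list did not pass either (camera adjusted p = 0.943), with 6 higher and 4 lower when adjusted over the list alone. SH2B1, ICAM1 and TIMP1 lost their calls without Control replicate 3 (edgeR adjusted p = 0.164, 0.0690 and 0.155), and SOCS2 and VEGFA without Control replicate 1 (0.0613 and 0.160).

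Leptin-treated cells lost most of the transcript of the actin-bundling protein gene LCP1, which fell from 83.8 ± 7.34 to 6.08 ± 1.43 CPM (n = 3 each). Its log2 fold change was -3.79 ± 0.17 (edgeR adjusted p = 2.19e-06). AMTN, a gene of mineralizing tooth matrix, fell from 66.9 to 11 CPM, and the basal keratin gene KRT14 fell from 10.6 to 1.43 CPM. The matrix protein gene POSTN fell from 5.75 to 0.639 CPM, the gap junction gene GJA1 from 7.45 to 1.47 CPM and IGFBP5, which encodes an IGF-binding protein, from 22.6 to 4.75 CPM. OPRPN had 56 to 79 counts in each control library and 2, 0 and 4 counts in leptin replicates 1, 2 and 3. In the other direction, SEZ6L2 rose from 0.863 ± 0.121 to 7.53 ± 1.71 CPM, a log2 fold change of 3.11 ± 0.28 (edgeR adjusted p = 0.000454). The calcium channel gene CACNA1H rose from 0.319 to 3.27 CPM, and CACNG4, of a channel-associated family, from 0.875 to 4.93 CPM. The adaptor gene SHC2 rose from 0.651 to 4.77 CPM, the collagen gene COL9A2 from 1.84 to 9.28 CPM and INHBE, an activin subunit gene, from 2.24 to 13.1 CPM.

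**Figure D1:**
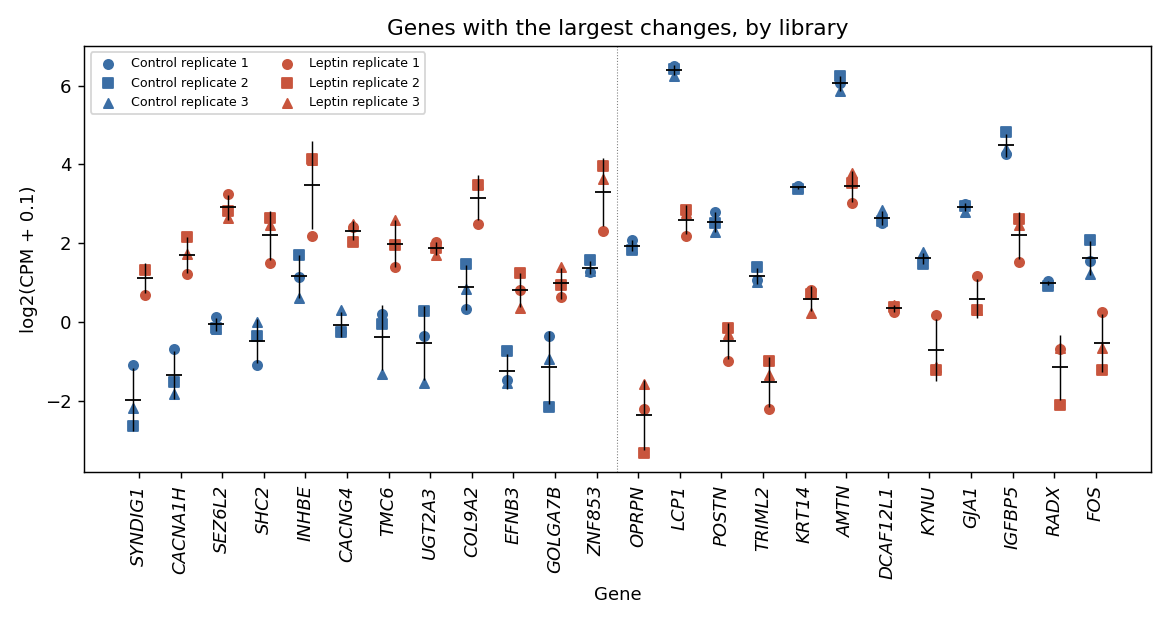
Expression of the 12 genes with the largest rise and the 12 with the largest fall, as log2(CPM + 0.1) on the vertical axis for each gene on the horizontal axis. Points are libraries and black bars are the mean and SD of 3 libraries; LCP1 lies at 75.8 to 90.2 CPM in controls and at 4.44 to 7.08 CPM with leptin.

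These genes were drawn from a comparison of 15685 tested genes, of which 1538 changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 896 higher and 642 lower with leptin. At least 2-fold changes were found for 377 genes, 249 higher and 128 lower. At an unadjusted p under 0.05 there were 4334 genes. The 3 leptin libraries lay entirely on one side of the 3 controls for 5045 genes, 32.2% of those tested, where chance gives 10%. LCP1 lies on chromosome 13 at 46125920 to 46211871 (hg38, minus strand) and SEZ6L2 on chromosome 16 at 29871159 to 29899550 (minus strand). AMTN (chromosome 4, 70518569 to 70532743) and OPRPN (chromosome 4, 70397931 to 70410195) are close together on the plus strand. Of the 24 genes with the largest changes, 12 overlap another annotated gene and 11 of these one on the opposite strand, and read pairs over exons of both genes were not counted. TMC6 alone overlapped a gene, TNRC6C, with over 0.1 of its counts, so its rise from 0.741 to 4.09 CPM is uncertain.

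The size of this gene count changed when single libraries were left out. It was 115 without Control replicate 1, 366 without Control replicate 2 and 170 without Control replicate 3, and it was 4761, 788 and 268 without leptin replicates 1, 2 and 3. At 2-fold the same leave-outs gave 85, 201, 112, 945, 217 and 122 genes. Of the 24 genes with the largest changes, 14 passed in all 6 leave-outs, LCP1, AMTN, KRT14, POSTN, GJA1, IGFBP5, OPRPN, SEZ6L2, CACNA1H, CACNG4, SHC2 and COL9A2 among them. INHBE did not pass without Control replicate 1 (edgeR adjusted p = 0.115), nor did UGT2A3 (0.0698), EFNB3 (0.108), ZNF853 (0.0696) and RADX (0.106). FOS did not pass without Control replicate 2 (edgeR adjusted p = 0.0839), SYNDIG1 (0.0569) and KYNU (0.0727) without Control replicate 3, and TMC6 (0.0666) and GOLGA7B (0.125) without leptin replicate 3. Of the 81 called genes named for the gene lists, 14 passed in all 6 leave-outs. By library, 14, 30 and 20 passed without Control replicates 1, 2 and 3, and 81, 45 and 27 without leptin replicates 1, 2 and 3. Where a lost call is given with 1 leave-out, above or below, that leave-out had the highest adjusted p. Many of these calls were also lost in other leave-outs. Each leave-out has 1 library fewer and so less power, and a lost call need not mean that the effect itself changed. Over the 6 leave-outs the log2 fold change ranged from -0.72 to -0.61 for CCNA2 and from 0.52 to 0.88 for VEGFA, both of which lost their calls without Control replicate 1. Changes also followed GC content. In the fifth of tested genes with most GC, 536 genes rose and 18 fell, while in the fifth with least GC 23 rose and 223 fell. Across 15249 genes, which are not independent replicates, Spearman's rho between log2 fold change and GC content was 0.39. With the GC trend of each library removed, an alternative chosen after seeing the data, 878 genes passed (457 higher, 421 lower), and 735 of them were among the 1538. All 24 genes with the largest changes still passed, but when 1 library was also left out 10 of them passed in all 6 leave-outs. CACNA1H, SHC2, COL9A2 and TRIML2, which passed throughout as tested, were lost without leptin replicate 3 and also without some control replicates. Of the 81 called list genes 57 passed with the trend removed, and 4 (POSTN, KRT19, RRM2 and MCM4) in all 6 leave-outs with it removed. Among the 24 lost on removal alone were SH2B1, FZD7, MSI1, CLDN3, CRB3, RFNG, DTX1 and CFD.

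**Figure D2:**
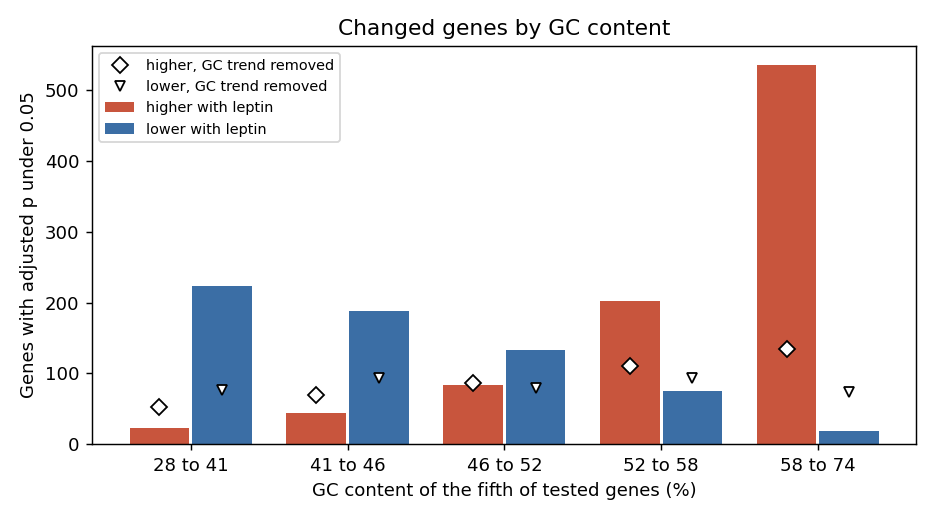
Number of genes changed with leptin (vertical axis) in 5 bins of equally many tested genes by GC content in percent (horizontal axis). Bars are the counts as tested, 536 higher and 18 lower in the fifth with most GC, and open symbols are the counts with the GC trend removed, 134 higher and 74 lower there.

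Genes of cell division were lower with leptin. Of 29 tested genes of cell cycle and mitosis, 23 fell and 0 rose, and all 29 had a negative log2 fold change, with a median of -0.68. The spindle regulator DLGAP5 fell from 42.7 to 19.8 CPM, the mitotic kinesin KIF11 from 48.3 to 27.9 CPM and the cyclin gene CCNA2 from 103 to 65.8 CPM. Of 30 genes of DNA replication and E2F targets, 19 fell and 0 rose (median log2 fold change -0.56). RRM2, a ribonucleotide reductase subunit gene, fell from 148 to 69.6 CPM, and the replicative helicase gene MCM4 from 282 to 155 CPM. Of 29 genes of homologous recombination and DNA repair, 8 fell and 0 rose, including FANCI (70.3 to 44.8 CPM) and the helicase gene BRIP1 (29.6 to 15.0 CPM). The lower counts adjusted over the list alone were 29, 24 and 16, with 1 repair gene higher. Each list passed camera with its preset correlation (adjusted p = 1.37e-23, 2.37e-20 and 3.95e-06). None passed with an estimated correlation (adjusted p = 0.401 for each), while fry, which tests a list on its own, gave an adjusted p of 0.031 for each. After removal of the GC trend 22, 18 and 4 genes of these lists fell. CCNA2 lost its call without Control replicate 1 (edgeR adjusted p = 0.0647), as did FANCI (0.0701) and BRIP1 (0.0604).

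Chaperone genes were lower as well. Of 16 heat shock proteins, 8 fell and 0 rose. The cytosolic chaperone genes HSP90AA1 and HSP90AB1 fell from 1225 to 536 CPM and from 1411 to 810 CPM, and HSPH1 fell from 130 to 64.5 CPM. Of 24 genes of the unfolded protein response list, 5 fell and 0 rose, including the endoplasmic reticulum chaperone gene HSP90B1 (489 to 298 CPM) and the disulphide isomerase gene PDIA4 (144 to 81.0 CPM). When adjusted over the list alone, 12 heat shock genes were lower and 1 higher, and 6 unfolded protein response genes were lower. Both lists passed camera (adjusted p = 7.34e-10 and 0.000124) and fry (0.031 and 0.00742), but not camera with an estimated correlation (adjusted p = 0.401 and 0.307). After removal of the GC trend 7 heat shock genes and 5 unfolded protein response genes fell. Without Control replicate 1, HSP90AA1 (edgeR adjusted p = 0.0547), HSP90AB1 (0.0563), HSP90B1 (0.108) and PDIA4 (0.0745) lost their calls.

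Targets of the transcription factor ATF4, which responds to amino acid shortage among other stresses, moved the other way. Of 31 tested genes of this amino acid stress response list, 15 rose and 0 fell, and 30 had a positive log2 fold change (median 0.54). The mTORC1 inhibitor gene DDIT4 rose from 215 to 570 CPM, SLC3A2, of an amino acid transporter, from 628 to 1240.1 CPM, STC2 from 7.11 to 22.8 CPM and CBS, of cysteine synthesis, from 4.47 to 11.4 CPM. There were 21 higher when adjusted over the list alone. The list passed camera (adjusted p = 2.57e-12), but neither camera with an estimated correlation (adjusted p = 0.536) nor fry (adjusted p = 0.103). The median difference of these genes from the control mean was 0.25 in leptin replicate 1 and 0.70 in each of leptin replicates 2 and 3, on the log2 scale. With the GC trend removed 12 genes of the list rose. Without Control replicate 1, SLC3A2 (edgeR adjusted p = 0.104) and DDIT4 (0.0537) lost their calls, and STC2 did so without Control replicate 3 (0.0923). Of 22 genes of the NOTCH pathway and targets list, 4 rose and 0 fell: HES7, RFNG, DTX1 and HES6, the last from 19.95 to 56 CPM. There were 5 higher adjusted over the list alone. This list passed camera (adjusted p = 0.00157), but not with an estimated correlation (adjusted p = 0.550), with fry (0.103) or with the GC trend removed (camera adjusted p = 0.0637). HES7 kept its call in 2 of 6 leave-outs, and RFNG, DTX1 and HES6 each in 1. The highest edgeR adjusted p was 0.0742 for HES7 and 0.148 for DTX1, both without Control replicate 3. For RFNG and HES6 it was 0.106 and 0.147, both without Control replicate 1.

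**Figure D3:**
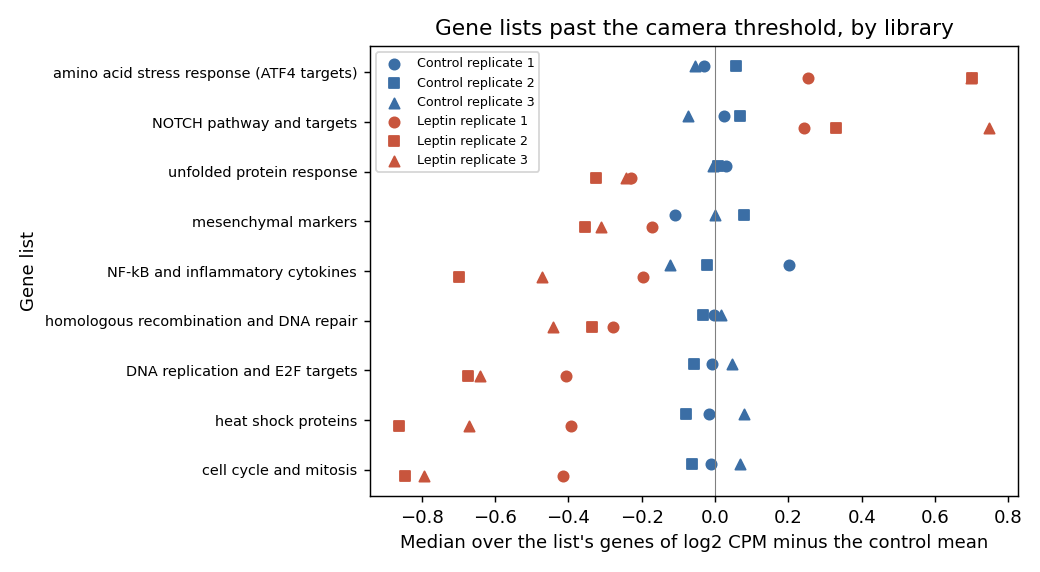
Median over each list's genes of log2 CPM minus the mean of the 3 controls (horizontal axis), for the 9 lists that passed camera (vertical axis), with 1 point per library. For cell cycle and mitosis, leptin replicate 1 lies at -0.42 and leptin replicates 2 and 3 at -0.85 and -0.79.

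Among mesenchymal markers, TNC, which encodes tenascin C, fell from 272 to 134 CPM and TAGLN, of an actin-binding protein, from 35.0 to 21.3 CPM. These were the 2 of 24 tested genes that changed. Counts adjusted over the list alone were 6 lower and 1 higher. Of 26 NF-kB and inflammatory cytokines genes, 6 fell and 2 rose. The chemokine gene CXCL8 fell from 109 to 49.8 CPM and the cytokine gene IL1A from 38.0 to 21.5 CPM, while LTB and ICAM1 rose. Adjusted over the list alone 10 were lower and 4 higher. Both lists passed camera as lower (adjusted p = 0.00737 and 0.0150), but not with an estimated correlation (adjusted p = 0.491 and 0.642) or fry (0.0759 and 0.216). The mesenchymal list lost its camera call without Control replicate 2 (adjusted p = 0.0514), and the NF-kB list without leptin replicate 1 (0.0600). Both passed with the GC trend removed (camera adjusted p = 0.00295 and 0.000694). TAGLN and LTB lost their calls without Control replicate 3 (edgeR adjusted p = 0.196 and 0.0597), IL1A without Control replicate 1 (0.0641) and CXCL8 without leptin replicate 3 (0.0588). In all, 9 of 33 tested lists passed camera, 2 higher and 7 lower. When the same 6 libraries were split 3 against 3 in the 9 other ways, up to 11 lists passed, so the number of lists does not set the treatment apart from other splits.

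Of 22 tested stemness markers, to which the study's question refers, 2 rose and 2 fell. The WNT receptor gene FZD7 rose from 65.5 to 87.3 CPM and MSI1, of an RNA-binding protein, from 4.404 to 7.51 CPM. The aldehyde dehydrogenase gene ALDH1A3 fell from 5.97 to 2.57 CPM and the DNA methyltransferase gene DNMT1 from 319 to 237 CPM. Adjusted over the list alone 2 were higher and 4 lower. The list did not pass camera (adjusted p = 0.795), and its median and mean log2 fold changes of 0.04 and 0.08 had the opposite sign to the direction camera gave. FZD7, MSI1 and DNMT1 lost their calls without Control replicate 3 (edgeR adjusted p = 0.195, 0.207 and 0.151), and ALDH1A3 without Control replicate 1 (0.0943). Of 12 multidrug transporters 0 changed (edgeR; camera adjusted p = 0.396). Among 20 epithelial markers, KRT19 fell from 102 to 38.7 CPM, while CLDN3 and CRB3 rose (camera adjusted p = 0.401). CLDN3 lost its call without Control replicate 3 (edgeR adjusted p = 0.0833) and CRB3 without Control replicate 1 (0.135).

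Markers of other cell types were measured in the same libraries. Of 12 tested fibroblast markers, POSTN and MFAP5 fell and FBLN1 rose, the last from 89.4 to 156 CPM (camera adjusted p = 0.0621), with 2 higher and 3 lower when adjusted over the list alone. Of 17 immune cell markers 1 was tested, CSF1R, at 2.11 CPM in controls and 3.64 CPM with leptin. Its leptin libraries all lay above the controls. By edgeR it did not pass over all tested genes (adjusted p = 0.130). It counted as 1 higher over the list alone only because a list of 1 tested gene leaves its edgeR p of 0.0281 unadjusted. Neither of the 2 tested endothelial markers, KDR and ERG, passed by either adjustment, and of 4 tested adipocyte markers CFD rose, from 23.5 to 43.4 CPM, a call lost without Control replicate 3 (edgeR adjusted p = 0.168). None of the 37 genes on the mitochondrial chromosome had a count in any library, so mitochondrially encoded genes were not tested. Leptin replicate 1 stood apart from the other leptin libraries. On the first principal component, with 49.6% of the variance, it stood at -2.15, the controls between -31.0 and -23.6, and leptin replicates 2 and 3 at 46.3 and 39.6. On the second, with 18.6% of the variance, it stood at -40.01, outside the other 5 libraries, which lay between -6.13 and 19.6. The median SD of log2 CPM between replicates was 0.24 in the leptin group and 0.12 in the control group.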

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

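The alternatives with the GC trend removed were chosen after seeing the data; the others were fixed beforehand. The 1538 genes changed by leptin became 2437 (1478 higher) with no filter on low counts and 274 (148 higher, 126 lower) at an adjusted p under 0.01. With the GC trend removed they became 878 (457 higher, 421 lower; 231 at least 2-fold, 137 of these higher), and with GC and length trends removed 577 were higher and 243 changed at least 2-fold (145 higher). In the leave-outs of 1 library, genes changed ranged from 115 to 4761 (higher 55 to 2583, lower 60 to 2178) and those at least 2-fold from 85 to 945 (higher 43 to 544, lower 42 to 401). With the GC trend also removed they ranged from 40 to 4071 (higher 16 to 2229, lower 24 to 1842), at least 2-fold 34 to 719 (higher 15 to 373, lower 19 to 346), and 8 to 16 lists passed, against 8 to 12 in the leave-outs without that removal. The cause was not tested. Of 81 named list genes that were called, 14 passed in all 6 leave-outs, and all 81 passed without leptin replicate 1. Scaling by library totals gave 1504 genes, 48.9% of them higher against 58.3%. DESeq2 gave 2133 and limma-voom 1325. No gene called both there and among the 1538 had the opposite sign under any alternative listed.

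Of the 9 lists past camera, 0 passed with an estimated correlation and 5 with fry, and the same numbers, 0 and 5, passed with the GC trend removed. Replicate numbers did not pair the samples: the correlation of deviations between same-numbered libraries was -0.05, 0.01 and -0.11. With the replicate block 1303 genes passed, and 919 (479 higher; 237 at least 2-fold, 135 of these higher) with the replicate block and the GC trend removed. Leaving out mitochondrially encoded genes removed no tested gene and tests nothing. At this depth a count of 0 in a library allows up to 0.192 CPM.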

Other observations

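Tests of the splits of the gene and list counts, of depth and of chromosome windows were set out before their results were seen, except that for genes changed at least 2-fold; the tests of GC content, of leptin replicate 1, of culture density and of endoplasmic reticulum stress were chosen after, and the mixture and label tests of leptin replicate 1 were made stricter after a first run. Some genes of 5 lists that did not pass camera changed with leptin, where 9.8% of all tested genes were called. Of those named next, SESN2, DDIT4 and STC2 are also members of the ATF4 target list. Of 25 p53 targets 3 rose and 1 fell: the cyclin-dependent kinase inhibitor gene CDKN1A rose from 33.1 to 85.2 CPM, the apoptosis gene BBC3 from 13.8 to 32.7 CPM and SESN2 from 36.2 to 91.2 CPM, while PLK2 fell (camera adjusted p = 0.401). Of 24 hypoxia response genes 5 rose and 1 fell, with DDIT4, STC2, VEGFA and ADM among the higher and ERO1A lower (camera adjusted p = 0.401). Of 25 oxidative stress response genes 3 rose, FTH1 of ferritin from 9948 to 14360.3 CPM among them, and 1 fell (0.351). Of 29 autophagy and lysosome genes 4 rose and 0 fell, including SQSTM1 from 899 to 1621 CPM (0.114), and of 18 FOXO and starvation response genes TXNIP rose (0.258). Each of the genes named here lost its edgeR call when 1 library was left out, for example CDKN1A without leptin replicate 2 (adjusted p = 0.110) and SQSTM1 without Control replicate 1 (0.138), and CDKN1A, SQSTM1 and ERO1A also lost it with the GC trend removed.

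The other tested lists did not pass camera either. Immediate early genes had 2 higher and 2 lower of 35 (adjusted p = 0.938), interferon-stimulated genes 2 and 3 of 33 (0.938), TGF-beta and SMAD targets 0 and 2 of 22 (0.401), YAP and TEAD targets 0 and 2 of 23 (0.938) and WNT targets 2 and 0 of 15 (0.401). Fatty acid synthesis had 1 higher and 1 lower of 23 (0.749), fatty acid oxidation 1 higher of 20 (0.534) and glycolysis 1 higher of 22 (0.281). Housekeeping genes had 0 higher and 2 lower of 25, TFRC and HPRT1 (0.257), calls kept in 2 and 1 of 6 leave-outs and lost without Control replicate 1 (edgeR adjusted p = 0.107 and 0.206). By edgeR there were 0 calls among 25 cholesterol synthesis genes (camera adjusted p = 0.0602), 33 nuclear genes of oxidative phosphorylation (0.654), 40 cytosolic ribosomal proteins (0.257) and 9 replication-dependent histones (0.575). The leptin libraries did not share a direction for cholesterol synthesis. Its median log2 difference from the control mean was 0.13, -0.64 and -0.45 in leptin replicates 1, 2 and 3.

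The real split of the libraries gave 1538 changed genes and 377 at least 2-fold, and the highest of the 9 other splits gave 0 of either, so 1 of 10 splits reached the real count. It gave 9 lists, and 4 of the 10 splits gave as many, the highest other split 11. With 10 splits no share below 0.1 is possible. Each other split keeps 2 leptin libraries on one side, so it holds part of any leptin effect. It also sets leptin and control libraries together on both sides, so any group difference widens the spread there and lowers the gene count. The gene counts of 0 are therefore no measure of chance. By list, a check chosen after that result was seen, the real split had the smallest camera p for cell cycle and mitosis, DNA replication and E2F targets, heat shock proteins, the unfolded protein response and homologous recombination, yet these lists also passed camera in 7, 7, 5, 1 and 4 of the 9 other splits. For the ATF4 targets, mesenchymal markers and NOTCH lists 2 of 10 splits had a p as small, and for NF-kB 4 did; these passed in 3, 3, 3 and 4 of the 9 other splits.

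The number of changed genes and its link with GC content have several possible explanations. Depth differed little, as the deepest library held 1.19 times the counts of the shallowest. After every library was thinned to the lowest total 1494 genes passed, but so slight a thinning could hardly lower the count, so this test decides little. A GC trend of the libraries as the whole cause is argued against by the 735 of 1538 called genes that still passed in the same direction with the trend removed. That removal used the GC content of each gene's longest transcript, so a bias by the GC content of the sequenced fragments may remain. When 1 library was left out as well, 40 to 4071 genes passed. For the GC-rich genes the matter stays open: 25% of the higher calls in the fifth with most GC still passed, but removal takes out any shift that follows GC content, whether from library preparation or from the cells. GC-rich minus GC-poor log2 CPM averaged -0.21 ± 0.08 in controls and 0.22 ± 0.11 with leptin (SD, n = 3 each), so trend and treatment cannot be told apart there.

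Leptin replicate 1, which stood outside all other libraries on the second principal component, lay at a median position of 0.347 between the controls (0) and leptin replicates 2 and 3 (1), over 945 genes changed at least 2-fold without it. A mixture with control RNA as the whole cause would need a share of 65.3%. Yet 24.5% of the 98 genes at least 4-fold lower in replicates 2 and 3 lay below the level this share requires. That argues against a mixture as the whole cause, while a smaller share joined with another difference was not tested. A control library carrying the leptin label is argued against as well, with limits. On 71.9% of the 945 genes replicate 1 lay beyond the 3 controls in the direction of the others. Any 1 control lay beyond the other 2 on at most 46.9%. These shares are unlike, since chance gives 25% beyond 3 libraries and more beyond 2. The 945 genes were also chosen against these 3 controls, which may raise the share of a library left out of that choice. With the GC trend removed the position was 0.368, which argues against GC content as its origin. For the 98 lower genes, a response weaker by 1 common share of the CPM difference would need the same level, so the 24.5% argues against that too. A response weaker by 1 common share of the log2 fold change can give lower levels, so these values do not decide on it. The position varied between genes, with quartiles of 0.112 and 0.657, so 1 median does not describe them all. This variation was not tested against the spread between replicates. A response weaker for some genes only therefore remains as an untested possibility, and so does a difference in the handling of this library.

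ATF4 targets were higher while heat shock and cell cycle genes were lower, and with the GC trend removed their medians of 0.50, -0.73 and -0.59 (log2 fold change), with 12, 7 and 22 genes past edgeR's test, argue against that trend as the whole cause. All 3 lists passed camera there at its preset correlation, but none with an estimated correlation (adjusted p = 0.416, 0.312 and 0.312; 0.536, 0.401 and 0.401 before removal), and the ATF4 targets did not pass fry (adjusted p = 0.103). The unfolded protein response list had a median of -0.28, with 5 genes lower and 0 higher. It passed fry (adjusted p = 0.00742) but not camera with an estimated correlation (adjusted p = 0.307). The list thus showed no rise of its genes, but it was known to be lower when this test was chosen. Nor can it test a route from endoplasmic reticulum stress to ATF4 that leaves these genes unmoved. Such stress as a source of the ATF4 target response stays undecided. Denser or more depleted leptin cultures may also give this pattern: the ATF4 targets stood 0.25 above the control mean in leptin replicate 1 and 0.70 in each of the others, so they varied among libraries of 1 dose. The labels state neither density nor whether the replicates are separate cultures, and this cannot be told apart from leptin.

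A hypothesis of regional copy-number differences between control and leptin cells was tested with the GC trend removed. Over 917 windows of 30 neighbouring genes the largest absolute median log2 fold change was 0.26, below the 0.3 set beforehand, and shuffled gene orders reached it with a permutation p of 0.146 (1000 orders). This argues against large regional differences, though it says nothing of single pairs of neighbours such as AMTN and OPRPN.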
